A study of Mus musculus with 12 samples.

How the data were processed

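Small RNA was sequenced from mouse embryonic stem cells of the E14 line (ESC) and from mouse trophoblast stem cells (TSC), the stem cells of the placental lineage. Each cell type was sampled as untreated control cells and as cells paused by inhibition of mTOR, a kinase that drives growth. Per the labels' protocols, small RNA was isolated with a column kit, 10 ng was made into libraries with the SMARTer smRNA-seq kit and 12 cycles of PCR, and single-end reads of 75 bp were sequenced on a HiSeq4000 with an aim of about 15M reads per sample. The kit carries no molecular identifiers that the labels mention, so intervals and floors given here cover counting error only.

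The deposited files hold raw counts, 1 whole number per mature miRNA arm for 1978 miRNAs, and were made by the authors from reads placed on the mouse genome build GRCm38, per the submitters' processing notes. The aligner, the counting tool, the miRNA annotation release, the trimming and the treatment of reads that match several loci are not given in the sources used here. Whole numbers with totals that differ between libraries are what unnormalised counts look like, and no scaling by the authors was found in the values.

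The labels list 12 samples, 3 per group. In each of the 4 groups the file of replicate 3 is identical to the file of replicate 2 at all 1978 miRNAs, so the pair was counted as 1 library. The comparisons therefore rest on 8 distinct libraries, 2 per group. The labels do not state that the libraries came from separate cultures, so the spread between these samples, on which p-values rest, may be technical. The total count per library ran from 13607 to 115492, at most 0.77% of the reads aimed for. A floor of 3 counts, the upper limit that a count of 0 allows, is worth 26.0 CPM (counts scaled to a common library size) in the deepest library and 220 CPM in the shallowest.

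Counts were analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M-values (TMM), and 206 miRNAs passed edgeR's filterByExpr with its default minimum of 10 counts at the median depth, worth about 369 CPM before scaling, in at least 2 libraries. These 206 held at least 98.14% of the counts of each library, and 1330 miRNAs had no count in any library. A quasi-likelihood model with 1 mean per group was fitted to all 4 groups at once, with 4 residual degrees of freedom and a common dispersion of 0.0456, a biological coefficient of variation of 21.3%. The spread of single miRNAs was drawn fully to the common trend (prior degrees of freedom: infinite). The edgeR p-values therefore rest on a spread pooled over miRNAs and groups, not on that of each miRNA between its own libraries. The contrasts were paused against control in each cell type, the difference of those pause effects, and ESC against TSC in each state. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum, in two-sided tests. CPM values are scaled with the TMM factors, and every mean is given with its SD over 2 libraries.

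For 30 miRNA lists fixed before the data were examined (clusters, seed families, markers of other cell types and entries of doubtful origin), called members were counted over all tested miRNAs and again adjusted over the list alone. The 17 lists with 3 or more tested members were also tested with camera in limma 3.58.1, at a preset correlation of 0.01, with adjustment over the lists. Camera was repeated with an estimated correlation, and the self-contained test fry was run beside it. The share of all counts that fell on each list was compared within a cell type by an exact two-sided permutation test, which cannot go below p = 0.33 with 2 libraries against 2.

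The miRNAs named in the text follow a rule set before the data were examined. For each comparison of groups these are the 10 with the highest and the 10 with the lowest fold change among called miRNAs with a mean of at least 100 CPM in a group and no overlap between the libraries of the groups. For the difference of pause effects they are 5 in each direction, without the overlap condition. Added to these are up to 4 of the most abundant members of each list and the 10 most abundant miRNAs of each group. Other called list members named as examples were chosen after their values were seen. Where a group held 0 counts of a miRNA, a fold is given as a bound, computed against a floor of 3 counts over the group. The counted group enters at its observed value, so the bound leaves out that group's own counting error. Where a group held 1 to 3 counts, the ratio of pooled counts is given with its 95% counting interval.

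The alternatives tried were DESeq2 1.42.0, other scalings (median of ratios in edgeR, total count alone, TMM computed without the miR-290-295 cluster), no filter, a filter at 10 CPM, every deposited file counted as a library, fits on only the groups compared, a fold minimum, the replicate number as a block, and each library left out in turn. Thinning of all libraries to the shallowest total and leaving out the doubtful entries were added after the data were seen. The procedure was tested on simulated counts for the ESC pause comparison (20 runs, 200 miRNAs changed, a median of 175.5 miRNAs tested). Of the changed miRNAs that passed the filter, it called 38% of those changed 2-fold and 90% of those changed 4-fold. Changed miRNAs that were not tested do not enter these percentages. Of its calls 3.3% were false and 0 were in the wrong direction. In the unchanged comparison it made 0 calls on average. Of 281 list tests with no change, 1 was called. The simulated miRNAs varied independently at 1 common dispersion. The simulation therefore cannot show how camera or the false calls behave where list members vary together or the spread differs between miRNAs. Rises and falls were equal in number, and the groups otherwise shared 1 mean profile. False calls from scaling, under a lopsided change or between unlike cell types, were therefore not simulated.

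Hairpin positions come from the GENCODE annotation of GRCm38, matched by name to 1845 of the 1978 miRNAs, and say where the named hairpin lies, not which locus the reads came from. The count of a miRNA with several genomic copies or a near-identical relative is uncertain, because the treatment of such reads is not known.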

Results

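The data collected were counts of mature miRNAs in mouse embryonic stem cells (ESC, line E14) and trophoblast stem cells (TSC), each as control cells and as cells paused by mTOR inhibition, which puts cells into a reversible dormant state like that of embryos in diapause. The design asks which miRNAs change when cells enter this state. Of the 12 samples labelled, the third of each group held the same values as the second at all 1978 miRNAs and was counted with it as 1 sample, which leaves n = 2 libraries in each of the 4 groups. The total counts were 19266 and 13607 in control ESC, 73574 and 61749 in paused ESC, 115492 and 18725 in control TSC, and 23652 and 30487 in paused TSC. Depth was therefore shallow and uneven, and a miRNA entered the tests only where at least 2 libraries reached about 369 CPM before scaling.

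The miR-290-295 cluster (GRCm38 chromosome 7, 3218626 to 3220841), the main miRNA cluster of early mouse embryonic cells, was the largest source of counts among the lists in every library (48.6% to 65.3%). It held 63.4% ± 1.76 of counts in control ESC, 65.2% ± 0.109 in paused ESC, 51.9% ± 4.68 in control TSC and 58.6% ± 0.705 in paused TSC (SD, n = 2). The most abundant miRNA was miR-290a-5p in 7 libraries and miR-291a-5p in 1 library of paused ESC, at 10.8% to 13.5% of counts. In at least 1 group the 10 most abundant also held miR-291a-3p, miR-292a-5p, miR-292a-3p, miR-293-3p, miR-293-5p, miR-294-3p and miR-295-3p of the same cluster. Behind the cluster, ESC and TSC differed. The miR-17-92 cluster and its paralogs, which are linked to Myc and proliferation, held 14.0% ± 1.43 of counts in control ESC and 2.72% ± 0.548 in control TSC, with miR-19a-3p and miR-17-5p among the 10 most abundant miRNAs of control ESC. The X-linked miR-322/miR-503 cluster held 10.7% ± 0.820 in control TSC and 0.126% ± 0.0394 in control ESC. The 10 most abundant held miR-322-5p in both TSC groups, miR-130a-3p and miR-301a-3p in paused TSC, and miR-5126 and miR-2137 in control TSC, the latter database entries thought to hold fragments of other RNAs. The first principal component of the tested miRNAs separated ESC from TSC with 80.88% of the variance. The second held 9.83% and separated paused from control ESC, and the third held 4.42% and separated paused from control TSC.

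**Figure D1:**
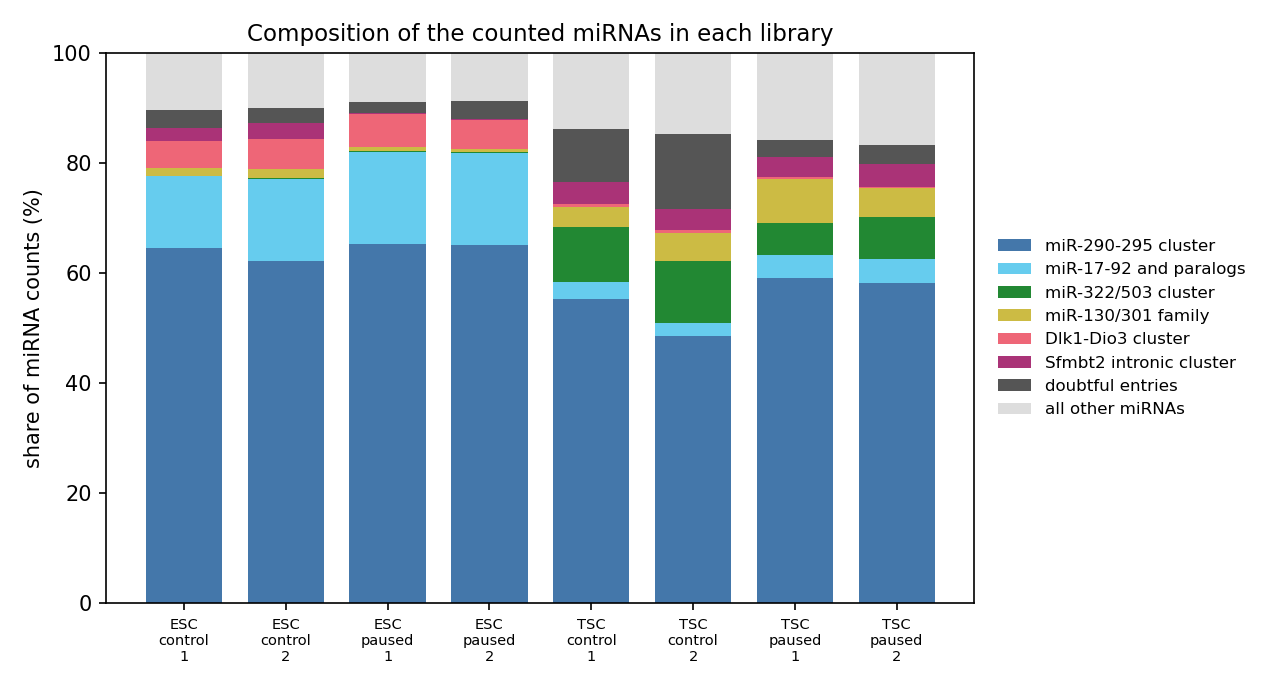
Share of the miRNA counts (percent, vertical axis) that fell on 7 miRNA lists and on all other miRNAs in each of the 8 libraries (horizontal axis, cell type, state and replicate). The miR-290-295 cluster took 48.6% to 65.3% of counts, the Sfmbt2 intronic cluster nearly vanished from the 2 paused ESC libraries, and the doubtful entries shrank in the 2 paused TSC libraries.

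Several miRNAs with more than 1 genomic copy carried no counts in these files. The arms miR-16-5p, miR-26a-5p, miR-24-3p, miR-30c-5p, miR-125b-5p, miR-181a-5p and let-7c-5p stood at 0 in all 8 libraries, while let-7a-5p had 2 counts and let-7f-5p had 6 in total. Lists that contain them, such as the let-7, miR-15/16, miR-26, miR-30, miR-125 and miR-181 families, are therefore measured by their other members only. In the Sfmbt2 intronic cluster, miR-669a-5p likewise had 0 counts, beside 359 on the copy-specific arm miR-669a-3-3p.

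In paused ESC the Sfmbt2 and miR-302/miR-367 clusters fell, while the miR-290-295 and Dlk1-Dio3 clusters held their shares of counts (65.2% and 5.63%). The Sfmbt2 intronic cluster, a set of miR-297, miR-466, miR-467 and miR-669 hairpins best known from trophoblast, fell almost as a block among its tested members. These were 20 of the 80 miRNAs on the list. Of the 81 hairpins named in the list 71 lie in the imprinted Sfmbt2 on chromosome 2 and 10 elsewhere. In all, 18 of its 20 tested members were lower in paused ESC (18 adjusted over the list alone) and 0 were higher. Of the 18 tested members whose matched hairpins all lie in Sfmbt2, 16 were lower. The list's share of counts was 2.58% ± 0.314 in control and 0.183% ± 0.00973 in paused ESC (SD, n = 2; exact permutation p = 0.33, the smallest that 2 against 2 allows). The best counted member, miR-669f-3p, dropped from 4064 ± 398 to 217 ± 42.7 CPM (log2 fold change −4.22 ± 0.42 SE, edgeR adjusted p = 5.08e-20), and miR-466f-3p dropped from 3457 ± 8.93 to 206 ± 7.70 CPM (−4.04). All 3 tested members of the miR-302/miR-367 cluster (chromosome 3, 127545228 to 127545807), which marks pluripotent cells and is higher in the primed state, also fell, with miR-367-3p at 1095 ± 259 CPM in control and 29.4 ± 24 CPM in paused cells. These 3 of the 10 miRNAs listed passed the filter through control ESC alone, so their direction and the list test are not independent of it. The share of counts on the whole list was 0.393% ± 0.152 in control and 0.00936% ± 0.00407 in paused ESC. In the other direction, 3 of 5 members of the miR-200 family, regulators of the epithelial state, rose (4 adjusted over the list alone): miR-200a-3p (log2 fold change 2.00), miR-200b-3p (1.80) and miR-429-3p (1.28), which share a locus on chromosome 4 (156053905 to 156055750).

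In all, edgeR called 57 of 206 miRNAs between paused and control ESC at an adjusted p under 0.05, 17 higher and 40 lower. Large decreases outside these clusters, at miRNAs with 20 or more counts in each group, were those of miR-3473b, from 3859 ± 688 to 147 ± 32.1 CPM (−4.69 ± 0.46 SE, adjusted p = 1.57e-20; chromosome 10, 41670739 to 41670793, intergenic), and of both arms of miR-142a, best known from blood cells: miR-142a-5p dropped from 4744 ± 1425 to 241 ± 100.1 CPM (−4.25, adjusted p = 6.74e-20) and miR-142a-3p from 2067 ± 602 to 137 ± 18.3 CPM (−3.86). Among the Sfmbt2 members, miR-669c-5p fell by 4.45 on the log2 scale. For members with few counts in paused ESC only bounds or ratios can be given. miR-669l-3p was at least 11.6-fold lower and miR-669f-5p at least 8.99-fold lower. The ratio of control to paused was 42.4 (95% counting interval 10.4 to 372) for miR-466m-3p, 46.2 (6.84 to 1977) for miR-466a-5p and 34.7 (4.81 to 1520) for miR-669e-5p. It was 84.8 (13.7 to 3498) for miR-302d-3p and 36.0 (11.1 to 185) for miR-302b-3p. Both arms of miR-34a, a known target of p53 (chromosome 4, 150068454 to 150068555), were lower: miR-34a-5p dropped from 4288 ± 263 to 1145 ± 174 CPM (−1.90, adjusted p = 1.82e-06) and miR-34a-3p fell by 1.83 on the log2 scale. In the miR-130/miR-301 family 3 of 5 members fell, among them miR-301a-3p (−1.89) and miR-130a-3p (−1.31), while miR-130b-5p rose (1.46). DESeq2 called 1 member of this family lower and 0 higher, and 1 of the 2 miR-34a arms lower. The adjusted p that DESeq2 gave miR-3473b was 4.56e-05.

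The largest increase in paused ESC among well counted miRNAs was that of miR-1949, from 575 ± 89.6 to 4007 ± 130 CPM (log2 fold change 2.78 ± 0.44 SE, adjusted p = 1.17e-08). Its hairpin lies on chromosome 18 (35554567 to 35554636), in an exon of the noncoding transcript AC121821.1 and an intron of Gm28285. miR-26b-5p, of a family linked to growth arrest, had 65 counts in paused and 1 in control ESC, a ratio of 16.9 (95% counting interval 2.92 to 676), and was not called by DESeq2. Its hairpin lies in an intron of Ctdsp1 (chromosome 1, 74394310 to 74394394). Increases of 1.43 to 2.04 on the log2 scale were called for miR-296-5p, miR-690, miR-29a-3p, miR-411-5p and miR-31-5p. DESeq2 did not call miR-690 (adjusted p = 0.0778), miR-411-5p (0.0834) or miR-31-5p (0.204). miR-25-3p, a paralog of the miR-17-92 cluster, rose from 9965 ± 1440 to 22150 ± 2623 CPM (1.15), and miR-92a-3p (0.97) and miR-363-5p (1.10) rose with it, 3 of 17 tested members of that list (2 higher and 1 lower with the total count alone, 1 higher with TMM without the miR-290-295 cluster). Within the miR-290-295 cluster 2 of 14 members were called lower (0 adjusted over the list alone; 3 higher and 2 lower with median-of-ratios scaling, 0 and 0 with TMM without the cluster), miR-291b-3p and miR-293-3p, the latter from 60264 ± 3888 to 34516 ± 5660 CPM. Of 33 tested members of the imprinted Dlk1-Dio3 cluster, miR-379-5p and miR-411-5p rose and miR-154-3p fell (5 higher and 0 lower with median-of-ratios scaling, 2 and 2 with the total count alone, 0 and 0 by DESeq2).

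Camera called 3 of the 17 lists on pausing of ESC: the Sfmbt2 cluster (adjusted p = 4.08e-13), the miR-302/miR-367 cluster (adjusted p = 0.00172) and the miR-200 family (adjusted p = 0.0118). With an estimated correlation these calls were lost, at adjusted p = 0.115 for Sfmbt2 and 0.272 for each of the others. The median log2 fold change was −3.99 over the Sfmbt2 members (−3.34 with sparsely counted members at their bound), −5.14 over the miR-302/miR-367 members (−3.78 at the bound) and 1.77 over the miR-200 family. The miR-302/miR-367 list had under 3 tested members without control replicate 2 and could not be tested there. Of the miR-200 family DESeq2 called 0 members (adjusted p = 0.107 for miR-200a-3p and 0.148 for miR-200b-3p), and leaving out 1 library raised the adjusted p to 0.0787 (control replicate 2) and 0.120 (control replicate 1). In the same way 1 missing library ended the call of miR-690 (0.124), miR-29a-3p (0.308) without control replicate 1, and of miR-296-5p (0.0629), miR-130b-5p (0.0976), miR-31-5p (0.110), miR-302b-3p (0.110) and miR-669l-3p (0.0679) without control replicate 2, while miR-26b-5p and miR-302d-3p could not be tested in 1 run each. With median-of-ratios scaling the split became 29 higher and 37 lower.

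**Figure D2:**
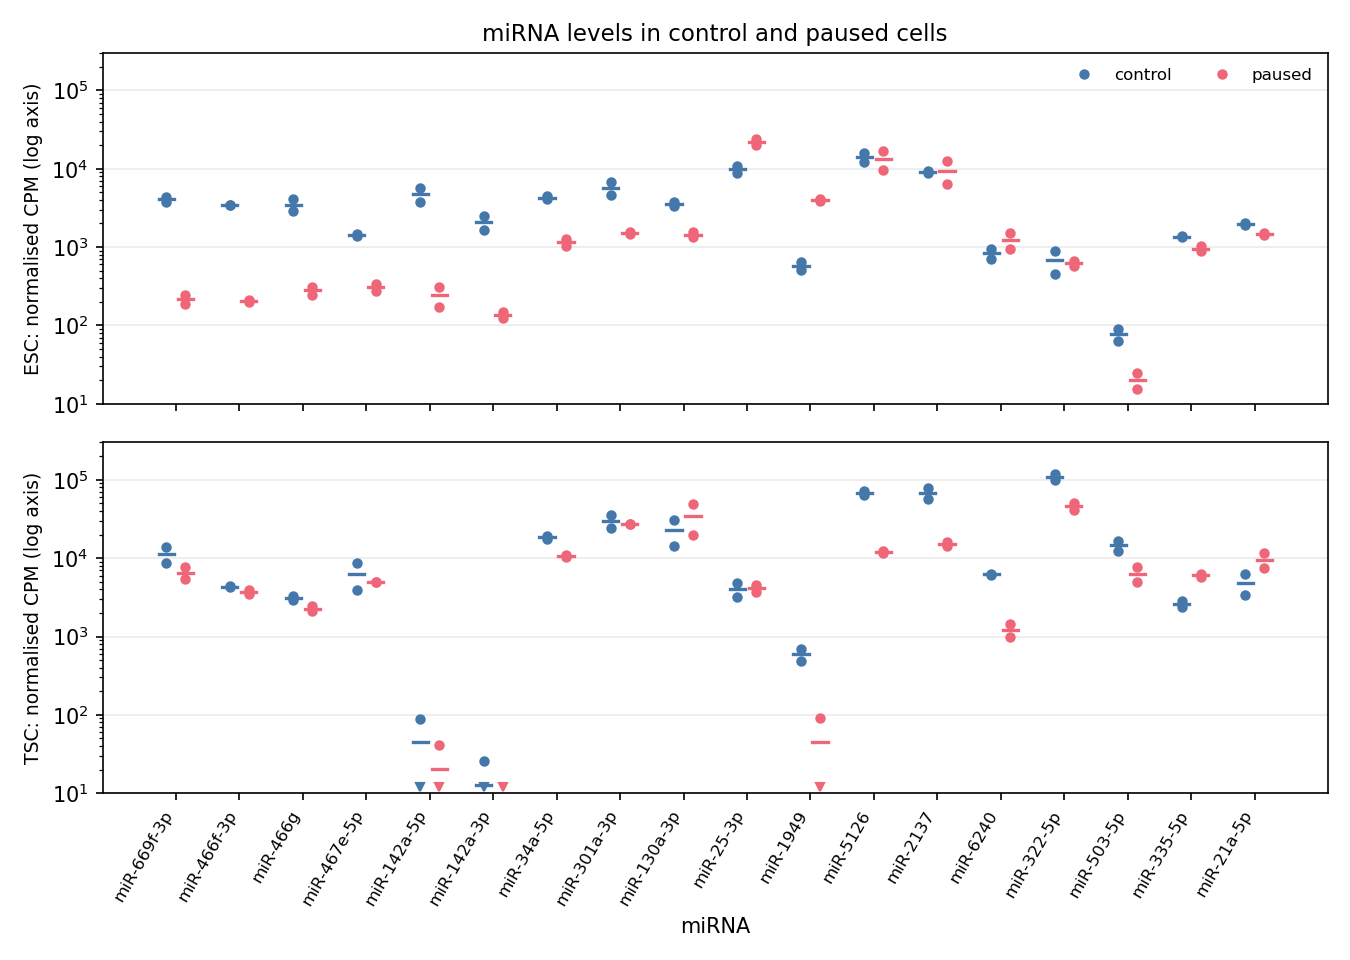
Normalised level (CPM, log axis) of 18 miRNAs in control (blue) and paused (red) ESC (upper panel) and TSC (lower panel). Points are libraries, short lines are means of 2 libraries, and triangles at the lower edge mark libraries with 0 counts. The members of the Sfmbt2 cluster (miR-669f-3p, miR-466f-3p, miR-466g, miR-467e-5p) and miR-142a lie far lower in paused ESC, while miR-5126, miR-2137 and miR-6240 lie lower in paused TSC.

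In paused TSC the miR-322/miR-503 cluster (chromosome X, 53047997 to 53054349), whose miR-322-5p shares its seed with the cell cycle repressors of the miR-15/16 family, had lower levels of its 2 main products: miR-322-5p dropped from 108477 ± 14404 to 46054 ± 7144 CPM (log2 fold change −1.24 ± 0.31 SE, edgeR adjusted p = 0.0012), and miR-503-5p from 14648 ± 3010 to 6290 ± 1881 CPM (−1.22, adjusted p = 0.0036). These were 2 of 8 tested members of the list. With the total count alone 1 of 8 was called. Of the 4 tested let-7 family members 3 were called lower, let-7i-5p (−2.32), let-7d-5p (−1.44) and let-7g-5p (−1.06), but 0 with the total count, with median-of-ratios scaling or by DESeq2. miR-203-3p, best known as a regulator of epithelial differentiation, dropped from 2739 ± 468 to 526 ± 16.4 CPM (−2.40, adjusted p = 5.23e-07; chromosome 12, 112130880 to 112130955). Higher in paused TSC were 4 miRNAs: miR-335-5p, whose hairpin lies in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), at 6014 ± 263 against 2605 ± 279 CPM (1.19, adjusted p = 0.01), miR-21a-5p at 9602 ± 3057 against 4800 ± 2021 CPM (0.97), miR-99b-5p (1.42), of a family reported to target Mtor, and miR-141-3p (1.37), of the miR-200 family. With TMM without the miR-290-295 cluster, the filter at 10 CPM, the replicate block within cell type or the fold minimum, 0 miRNAs were called higher.

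The largest change in composition in TSC was on the doubtful entries, whose share was 11.7% ± 2.80 of counts in control and 3.28% ± 0.25 in paused TSC (SD, n = 2; exact permutation p = 0.33). All 4 tested entries were lower (4 adjusted over the list alone), led by miR-5126, from 67750 ± 4731 to 12012 ± 504 CPM (−2.50, adjusted p = 7.37e-12), then miR-6240 (−2.35), miR-2137 (−2.16) and miR-5099 (−1.30). This was the 1 list of 17 that camera called (adjusted p = 0.00185), and with an estimated correlation the call was lost (adjusted p = 0.603). In ESC the entries held 2.95% ± 0.309 of counts in control and 2.59% ± 0.965 in paused cells, and 1 of 4, miR-5099, was lower (−2.23). Since scaling is by composition, the fall of these entries stands beside every other change in TSC.

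In all, 39 of 206 miRNAs were called between paused and control TSC, 4 higher and 35 lower. That split depended on the scaling: it was 14 higher and 12 lower with the total count alone, 6 and 18 with median-of-ratios scaling, and 0 and 28 with TMM computed without the miR-290-295 cluster. The median of all tested miRNAs was −0.386 (0.08 with the total count), and the total count moved single miRNAs by a median of 0.507, so decreases near 1 on the log2 scale are relative to that shift. The median also depended on single libraries with TMM kept. Over miRNAs tested in both fits, it was 0.0362 without control replicate 1 and −0.0653 without control replicate 2. It was 0 without paused replicate 1 and −0.139 without paused replicate 2. Other decreases named by the rule were those of miR-712-5p (−2.89), miR-712-3p (−2.78) and miR-376b-3p (−3.13 ± 0.56 SE, 967 ± 686 to 122 ± 2.15 CPM). miR-154-3p was at least 3.81-fold lower, and the ratio of control to paused was 12.6 (95% counting interval 4.13 to 63.0) for miR-1949, 10.2 (1.604 to 428) for miR-337-3p, 9.63 (1.496 to 404) for miR-379-3p and 6.02 (1.46 to 53.1) for miR-411-3p. Of the Dlk1-Dio3 cluster, 8 of 33 members were called lower, yet 25 of the 33 had 3 or fewer counts in paused TSC, and 3 were called with the total count alone, 4 with median-of-ratios scaling and 2 by DESeq2. Camera did not call the list (adjusted p = 0.0813), but did with the total count alone (adjusted p = 0.0019) and with any 1 library left out: 0.0371 without control replicate 1, 0.00587 without paused replicate 1, 0.0121 without control replicate 2 and 0.0441 without paused replicate 2. With an estimated correlation it stood at adjusted p = 0.603. The Sfmbt2 cluster, with 4.00% ± 0.0710 of counts in control and 3.94% ± 0.239 in paused TSC, had 3 of 20 members called lower (adjusted p = 0.304 for the list) and 0 with the total count.

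Single calls in TSC were fragile. DESeq2 called 16 miRNAs, and the count was 23 without control replicate 1, 13 without paused replicate 1, 32 without control replicate 2 and 7 without paused replicate 2. Of 14 miRNAs named by the rule, miR-335-5p, miR-5126 and miR-203-3p were called in each of those runs, but miR-335-5p not with TMM without the miR-290-295 cluster. The highest adjusted p with 1 library left out was 0.123 for miR-99b-5p, 0.164 for miR-141-3p, 0.211 for miR-21a-5p, 0.0543 for miR-712-5p and 0.0852 for miR-712-3p, all without paused replicate 2, 0.236 for miR-376b-3p and 0.423 for miR-154-3p without control replicate 1, and 0.0578 for miR-1949 without paused replicate 1. miR-337-3p, miR-379-3p and miR-411-3p were called in 0 of those runs and not by DESeq2.

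Across miRNAs, no correlation between the pause effects of the cell types was found. Over the 206 tested miRNAs, which are not independent replicates, Pearson's r between the log2 fold changes was 0.0446 (permutation p = 0.524) and Spearman's rho was −0.00777 (permutation p = 0.911), and 50.49% had the same sign. The 2 comparisons share no library. Noise could hide a relation. In paused ESC 9 of 20 Sfmbt2 members had 3 or fewer counts, and in paused TSC 25 of 33 Dlk1-Dio3 members did. 6 miRNAs were called lower in both cell types, where 6.80 are given by chance (Fisher's exact p = 0.818): miR-154-3p, miR-1983, miR-467d-5p, miR-5099, miR-669e-5p and miR-669l-3p. 0 were called higher in both (0.330 by chance; Fisher's exact p = 1), and 3 were called in opposite directions, miR-1949, miR-429-3p and miR-690, each higher in paused ESC and lower in paused TSC. The TSC call of miR-429-3p was lost with the total count, with median-of-ratios scaling and by DESeq2.

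Tested as a difference of pause effects, 54 miRNAs were called, 30 with the more positive effect in ESC and 24 with the more negative (17 and 40 with the total count alone). miR-1949 differed by 6.30 on the log2 scale (± 0.82 SE, edgeR adjusted p = 5.27e-12). miR-3473b differed by −5.01 (adjusted p = 2.93e-13), with 1698 CPM in control and 1785 CPM in paused TSC beside its fall in ESC, and miR-669c-5p by −4.38 (adjusted p = 3.55e-09), with 5584 and 5352 CPM in TSC. These 3 of the 10 miRNAs named by the rule were called with each library left out. Of them, miR-1949 had 3 or fewer counts in paused TSC, so the size of its difference is a fitted value and not a bound. The other 7 of the 10 also rest on groups with few counts or none: miR-26b-5p, miR-20b-5p, miR-154-3p and miR-150-5p had the more positive effect in ESC, and miR-669f-5p, miR-297c-5p and miR-188-5p the more negative. Without 1 library their adjusted p reached 0.0699 (miR-26b-5p), 1 (miR-20b-5p and miR-150-5p) and 0.365 (miR-154-3p) with control TSC replicate 1 left out, 0.0784 (miR-669f-5p) and 1 (miR-297c-5p) with control ESC replicate 2 left out, and 0.171 (miR-188-5p) with control ESC replicate 1 left out. DESeq2 called 1 of these 7, miR-20b-5p, and gave no adjusted p for 3. Its adjusted p was 2.91e-07 for miR-1949, 0.00469 for miR-3473b and 4.88e-08 for miR-669c-5p. By list, camera called the difference for the Sfmbt2 cluster (15 of 20 members called, 18 adjusted over the list alone, 9 by DESeq2; adjusted p = 7.85e-09), the Dlk1-Dio3 cluster (10 of 33, 13 adjusted over the list alone, 4 with the total count, 2 by DESeq2; adjusted p = 0.00363) and the miR-302/miR-367 cluster (0 of 3; adjusted p = 0.00222). With an estimated correlation none of these held, at adjusted p = 0.252, 0.377 and 0.377. All 3 tested miR-302/miR-367 members had 3 or fewer counts in each TSC group, so a change there was not detectable at this depth. Of the Dlk1-Dio3 members, 25 of 33 had so few counts in paused TSC. Their median pause effect in TSC was −1.487 as fitted and 0 with sparsely counted members at their bound, so the size of this difference is uncertain.

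**Figure D3:**
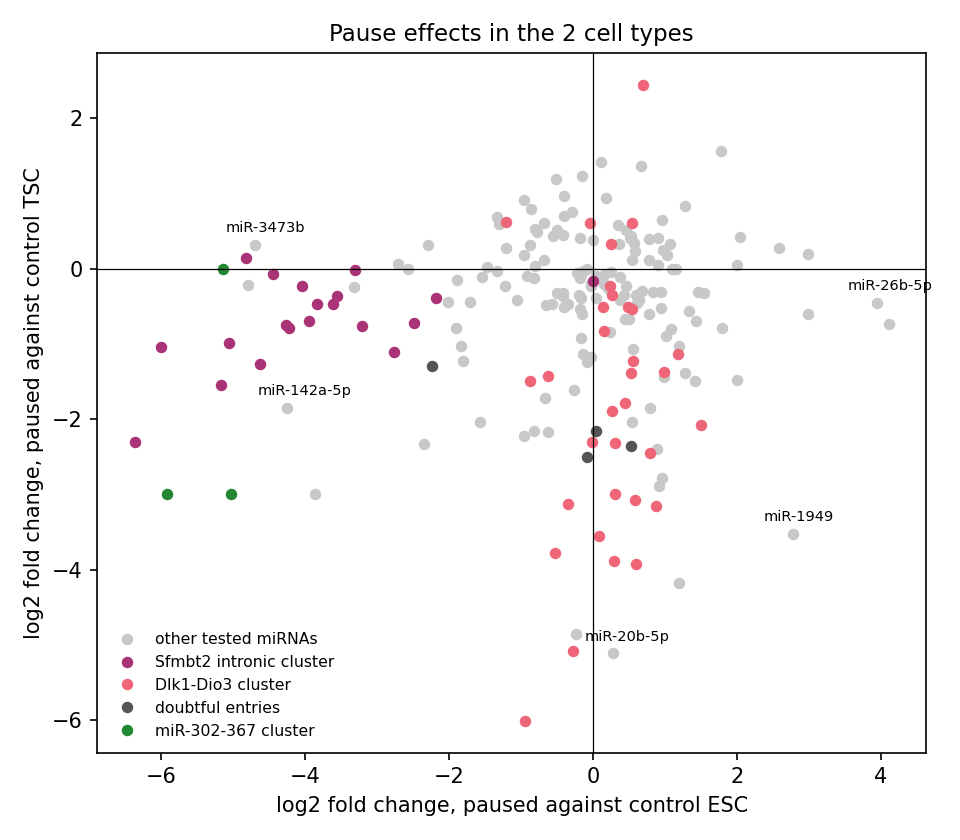
Fitted log2 fold change on pausing in ESC (horizontal axis) against that in TSC (vertical axis) for the 206 tested miRNAs, each point 1 miRNA, with 4 lists coloured and 5 miRNAs named. Points do not follow a diagonal (Pearson's r = 0.0446): the Sfmbt2 members spread to the left, and the doubtful entries and much of the Dlk1-Dio3 cluster lie below 0. Fitted values of miRNAs with 3 or fewer counts in a group are not bounds.

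Control ESC and TSC differed at 153 of 206 miRNAs, 69 higher and 84 lower in ESC (87 and 66 with median-of-ratios scaling, 89 and 63 with the total count, 79 and 61 with TMM without the miR-290-295 cluster). All 33 tested members of the Dlk1-Dio3 cluster (chromosome 12, 109563692 to 109747960), an imprinted locus whose miRNAs are active in ESC of full potency, were higher in ESC (32 by DESeq2), with a share of 5.22% ± 0.406 of counts against 0.451% ± 0.0119 in TSC (SD, n = 2). The share covers all 105 miRNAs listed, tested or not. Of the 33 tested, 6 had 3 or fewer counts in control TSC and 25 in paused TSC. Members that passed the filter through ESC alone favour a higher level there, so the number higher and the list test are not independent of the filter. All 8 members of the miR-322/miR-503 cluster were lower in ESC. By DESeq2 7 were. With median-of-ratios scaling, the total count or TMM without the miR-290-295 cluster 6 were, and miR-542-5p lost its call there and with replicate blocks. miR-322-5p stood at 675 ± 310 CPM in ESC and 108477 ± 14404 CPM in TSC (−7.37 ± 0.43 SE, edgeR adjusted p = 1.08e-53), miR-322-3p was at least 77.7-fold lower, miR-503-3p at least 9.49-fold lower and miR-542-5p at least 2.50-fold lower. The ratio of TSC to ESC was 201 (95% counting interval 68.6 to 975) for miR-503-5p, and miR-351-5p was lower by −5.70 on the log2 scale. In the miR-17-92 list 12 of 17 members were higher in ESC, above all products of the X-linked miR-106a-363 cluster (chromosome X, 52741693 to 52742567): miR-20b-5p at 13798 ± 1725 against 63.7 ± 90.1 CPM (7.06), miR-106a-5p at 9382 ± 73.1 against 74.7 ± 20.5 CPM (6.77), miR-363-5p at least 21.1-fold higher, and miR-363-3p with a ratio of 164.5 (28.5 to 6595).

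Further miRNAs higher in control ESC were miR-367-3p (at least 33.7-fold), miR-708-3p (at least 13.5-fold), miR-708-5p (ratio 190, 95% counting interval 33.0 to 7594), miR-142a-5p (4744 ± 1425 against 44.6 ± 63.05 CPM), miR-142a-3p (ratio 94.9, 25.4 to 798) and miR-485-3p (ratio 68.3, 11.3 to 2797). Higher in control TSC were miR-483-3p, from an intron of Igf2 on chromosome 7 (142654924 to 142654996; at least 13.7-fold), miR-291b-3p (22756 ± 2048 against 365 ± 64.1 CPM), miR-669i (at least 2.90-fold) and miR-210-3p, the classic hypoxia miRNA (ratio 47.2, 12.9 to 392). Camera called 7 lists: Dlk1-Dio3 (adjusted p = 1.47e-12), miR-322/miR-503 (adjusted p = 0.000646), miR-17-92 (adjusted p = 0.000936), Sfmbt2 (14 of 20 lower in ESC, or 9 lower and 1 higher with the total count alone and 6 lower by DESeq2; adjusted p = 0.0229), blood markers (3 of 3 higher in ESC; adjusted p = 0.0229), miR-302/miR-367 (3 of 3 higher; adjusted p = 0.0300) and stress and growth arrest (4 of 4 lower, 3 by DESeq2; adjusted p = 0.0459). None was called with an estimated correlation, at adjusted p = 0.0756 for Dlk1-Dio3, 0.188 for miR-322/miR-503 and 0.305 for the others. With 1 library left out, 17 of the 20 miRNAs named by the rule stayed called, and the highest adjusted p of the others was 0.0618 for miR-708-3p (control TSC replicate 1), 0.227 for miR-669i (control TSC replicate 2) and 0.185 for miR-542-5p (control ESC replicate 1).

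Paused ESC and TSC differed at 158 of 206 miRNAs, 77 higher and 81 lower in ESC, and all 20 miRNAs named by the rule were called by DESeq2 and with each library left out. Again all 33 Dlk1-Dio3 members were higher in ESC (32 by DESeq2): miR-494-3p was at least 26.9-fold, miR-154-3p at least 20.95-fold and miR-134-5p at least 20.2-fold higher, and the ratio was 225 (95% counting interval 40.1 to 8885) for miR-376c-3p and 136 (24.3 to 5403) for miR-379-3p. The products of the miR-106a-363 cluster had 0 counts in paused TSC, which puts miR-20b-5p at least 318-fold, miR-106a-5p at least 151-fold, miR-363-5p at least 27.7-fold and miR-363-3p at least 21.6-fold higher in ESC. miR-150-5p, another blood marker, was at least 86.9-fold higher. With the Sfmbt2 cluster low in paused ESC, 19 of its 20 members were lower in ESC than in TSC: miR-297c-5p was at least 121-fold, miR-467b-3p at least 26.98-fold and miR-669f-5p at least 15.2-fold lower. Outside it, miR-483-3p was at least 72.5-fold, miR-188-5p at least 30.4-fold and miR-152-3p at least 19.4-fold lower in ESC. The ratio of TSC to ESC was 314 (106.5 to 1528) for miR-503-5p and 216 (59.0 to 1800) for miR-33-5p, and the log2 fold change was −7.19 for miR-291b-3p and −7.12 for miR-351-5p. Camera called Dlk1-Dio3 (adjusted p = 3.18e-14), Sfmbt2 (adjusted p = 8.06e-07), miR-322/miR-503 (7 of 8 lower, 5 by DESeq2; adjusted p = 0.00570) and miR-17-92 (12 of 17 higher and 1 lower, 11 and 0 by DESeq2; adjusted p = 0.00925). With an estimated correlation these stood at adjusted p = 0.0578, 0.218, 0.226 and 0.560, and none was called.

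Counts on markers of other cell types were rare, except those of blood in ESC. Low counts do not show that such cells were absent, since markers with several genomic copies may have gone uncounted. The arms miR-129-5p, miR-138-5p, miR-1a-3p, miR-194-5p and miR-196a-5p, each shared by several copies, had 0 counts. The shared arms miR-128-3p and miR-219a-5p had 5 and 20. The neural, muscle and endoderm lists held at most 0.0225% of counts as a mean of any group and had 0 tested members. The fibroblast list held 0.107% ± 0.0169 of counts in control and 0.111% ± 0.0155 in paused ESC, and 0.0631% ± 0.0137 and 0.0476% ± 0.0163 in control and paused TSC, with 0 calls on pausing for its 1 tested member. The endothelial list held 0.0997% ± 0.00585 and 0.103% ± 0.00186 in control and paused ESC and 0.236% ± 0.0512 and 0.218% ± 0.0259 in control and paused TSC, again with 0 calls. The blood list held 1.00% ± 0.153 of counts in control ESC and 0.530% ± 0.0620 in paused ESC, with miR-150-5p higher and both arms of miR-142a lower on pausing, and camera did not call it (adjusted p = 0.334), but fry did, as lower (adjusted p = 0.0263).

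Few members of the remaining lists were called on pausing. In ESC, 1 of 2 members of the miR-29 family, the 1 tested member of the miR-26 family, miR-26b-5p, and 1 of 3 members of the miR-148/miR-152 family, miR-148a-3p (1.28), were higher. The miR-148a-3p call was lost with the total count, with TMM without the miR-290-295 cluster and by DESeq2, that of the miR-29 family with TMM without the miR-290-295 cluster, and that of miR-26b-5p by DESeq2. The let-7 (0 of 4), miR-15/16 (0 of 5), miR-99/100 (0 of 1), miR-125 (0 of 2), miR-30 (0 of 4), miR-101 (0 of 2), miR-181 (0 of 1), miR-23/24/27 (0 of 5), miR-183/miR-96/miR-182 (0 of 4), miR-322/miR-503 (0 of 8), stress (0 of 4) and non-canonical (0 of 1) lists had no edgeR call in ESC. With median-of-ratios scaling 1 member of the miR-15/16, 2 of the miR-23/24/27 and 2 of the miR-183/miR-96/miR-182 lists were higher there. In TSC, the miR-15/16 list had 2 of 5 members lower, miR-322-5p and miR-497a-5p (−2.23), or 1 with the total count, and its share of counts was 8.95% ± 0.493 in control and 5.34% ± 1.06 in paused TSC. The miR-183/miR-96/miR-182 list had 1 of 4 and the miR-23/24/27 list 1 of 5 members lower, but 0 each with the total count, with median-of-ratios scaling or by DESeq2. The miR-17-92 list had 2 of 17 members lower in TSC, miR-20b-5p and miR-106a-5p, both with 0 counts after pausing. Neither was called with the total count, by DESeq2, with TMM without the miR-290-295 cluster or adjusted over the list alone, and the total count gave 2 others as higher. The miR-200 list had miR-141-3p higher and miR-429-3p lower (−1.38), and the stress list had miR-21a-5p higher and miR-210-3p lower (−1.02). With the total count, with median-of-ratios scaling or by DESeq2 neither list had a lower member, and the miR-200 list had 2 higher members with the total count, 1 with median-of-ratios scaling and 0 by DESeq2. The miR-290-295, miR-302/miR-367, miR-34, miR-125, miR-29, miR-30, miR-26, miR-101, miR-148/miR-152, miR-181, miR-130/miR-301, non-canonical and blood lists had 0 edgeR calls in TSC, although the total count alone gave 2 higher members of the miR-130/miR-301 family and 1 each of the miR-290-295, miR-125 and miR-148/miR-152 lists. Of the miR-99/100 family, the 1 tested member, miR-99b-5p, was higher in TSC, with 0.0403% ± 0.00418 of counts on the family in control and 0.14% ± 0.0119 in paused cells, and was not called by DESeq2 or with TMM without the miR-290-295 cluster.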

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

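The test of the difference between the pause effects of ESC and TSC was planned before the data were examined, and the 3 tests of technical explanations in the last paragraph were chosen after the results were seen.

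The pause effect differed between ESC and TSC at 54 of 206 miRNAs by edgeR (adjusted p under 0.05). The adjusted p of the difference was 2.93e-13 for miR-3473b, 5.27e-12 for miR-1949 and 3.55e-09 for miR-669c-5p, and these 3 were called without any 1 library (highest adjusted p 0.00586, 1e-04 and 0.000349). miR-1949 had 22 and 579 counts in control and paused ESC against 63 and 3 in control and paused TSC. For the other named miRNAs with a sparsely counted group the adjusted p was 0.00374 for miR-26b-5p, 0.0146 for miR-669f-5p, 0.0156 for miR-297c-5p, 0.0159 for miR-20b-5p, 0.0232 for miR-154-3p, 0.0283 for miR-150-5p and 0.036 for miR-188-5p. Each of these 7 calls ended in at least 1 run with a library left out, as the report gives. miR-20b-5p had 10 counts in control and 0 in paused TSC, and miR-150-5p had 5 and 0, all of them in control replicate 1.

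By list, camera gave the difference an adjusted p of 7.85e-09 for the Sfmbt2 intronic cluster, 0.00222 for the miR-302/miR-367 cluster and 0.00363 for the Dlk1-Dio3 cluster, with 0.252, 0.377 and 0.377 when the correlation was estimated. The miR-302/miR-367 members had 3 or fewer counts in both TSC groups, and 25 of 33 Dlk1-Dio3 members had so few in paused TSC. The median pause effect of the Dlk1-Dio3 members in TSC was −1.487 as fitted and 0 with sparsely counted members at their bound.

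The fall of the Sfmbt2 cluster in paused ESC was weighed against 3 technical explanations. RNA like that of the control TSC in the control ESC libraries would have brought the miR-322/miR-503 cluster, yet that list stood at 0.8% of its level in control TSC, while the excess of the Sfmbt2 cluster was 40% of the TSC level. RNA of other cells, with another level of the miR-322/miR-503 cluster, was not tested. Depth does not account for it, since 11 of 14 tested members were lower with every library thinned to 13607 counts. Reads moving between near-identical members leave the sum of the list in place, and that sum was 12.4 times as high in the lowest control as in the highest paused library. A response of the cluster to the pause remains a hypothesis that may explain the fall, found and tested on the same data, with differences between cultures that the labels do not describe left open.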

How the results depend on the processing

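Thinning to equal depth and leaving out the doubtful entries were chosen after the results were seen, all other alternatives before. For the ESC pause, 57 calls became 37 with DESeq2, 94 with every deposited file counted and 30 with a fold minimum, and 41 to 47 with 1 library left out. For the TSC pause, 39 calls became 16 with DESeq2, 24 with median-of-ratios scaling, 16 with no filter, 18 thinned, 19 without the doubtful entries, 11 with a fold minimum, 19 with the compared groups alone, and 7 to 32 with 1 library left out. For the difference, 54 calls became 30 with DESeq2, 30 with no filter, 90 with every file counted, 27 thinned, 33 with a fold minimum, and 26 to 65 with 1 library left out. For control ESC against TSC, 153 calls became 100 with the compared groups alone (122 to 155 with 1 library left out), and for the paused cells no alternative moved the 158 calls by over 1.5 times. Counting every file treats identical files as replicates. A lone library in a group is assumed to vary like the others. Of the lists, 3 called in ESC became 0 with an estimated correlation, 5 with fry and 2 to 4 with 1 library left out. Thinned, 1 was called (Sfmbt2), and the miR-302/miR-367 and miR-200 lists had under 3 tested members and were not tested. Of the lists, 1 in TSC became 0 with an estimated correlation, 2 with the total count and 2 to 3 with 1 library left out. The median of the moves that scaling gave single miRNAs reached 0.141 (ESC), 0.507 (TSC), −0.603 (difference), 0.630 (control cells) and 0.668 (paused cells). Equal replicate numbers did not pair libraries (correlations −0.183 to 0.0829). As a block they gave 20 (shared) and 12 (within cell type) calls in TSC, 51 and 44 in ESC, and 45 and 31 for the difference. Over all alternatives, the miRNAs named stayed on the same side of the threshold 1325 times in ESC, lost their call 84 times and gained one 58 times. In TSC the tally was 1168, 197 and 35, and for the difference it was 137, 56 and 0, with 0 reversed. Uncalled list members enter the ESC and TSC tallies, so these do not measure how stable the calls were. Of the calls named by the rule, DESeq2 kept 13 of 20 in ESC, 9 of 14 in TSC and 4 of 10 for the difference. The filter at 10 CPM was looser than the one used.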

Other observations

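The tests of explanations and the arm ratios in this part were chosen after the results were seen.

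Within hairpins, the ratio of the 5p to the 3p arm was compared with limma where both arms had over 3 counts in each group compared. In ESC (33 hairpins, 8 with p under 0.05), the ratio of miR-324 fell by 2.59 on the log2 scale on pausing (SE 0.524, adjusted p = 0.0305). That of miR-363 rose by 1.66 (SE 0.348, adjusted p = 0.0305). The ratio of miR-293 rose by 1.43 (SE 0.34, adjusted p = 0.0404), but its adjusted p was 0.0561 when all 40 hairpins with tested arms were kept, sparse ones included. In TSC 0 of 32 were called (0 with p under 0.05), and 0 of 25 in the difference (5 with p under 0.05). Between control ESC and TSC 2 of 33 were called: miR-291b (2.30 higher in ESC, adjusted p = 0.0111) and miR-290a (−1.83, adjusted p = 0.0304). With all 40 hairpins kept 4 were called there and 2 in ESC.

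Of 39 calls on pausing of TSC 35 were lower. With the total count alone 53.8% of the calls were higher, and with the doubtful entries left out 42.1% were. Both settings moved the tested miRNAs nearly alike (median 0.507 and 0.393, interquartile range 0.0672 and 0.0356), which raises that percentage by itself, so neither shows which scaling is right or whether the excess is technical. Thinned to equal depth 27.8% were higher. Thinning also moved the miRNAs tested in both fits, by a median of 0.3605, which could raise that percentage too. The depth of the deepest library is therefore left open as well. The fall of the doubtful entries themselves held for 4 of 4 with TMM, with median-of-ratios scaling, with TMM without the miR-290-295 cluster and by DESeq2, and for 3 of 4 with the total count (median −1.83) and after thinning (median −1.99). A lower rate of RNA breakdown and a true change in the RNAs that give rise to these fragments were not tested.

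Among 13 hairpins with a counted copy-specific arm, 61.5% (8) had 0 counts on the arm shared by several copies, against 8.75% (14 of 160) of single-copy hairpins with a counted 5p arm (Fisher's exact p = 1.64e-05). miR-16 shows it: its copy-specific 3p arms had 111 counts and miR-16-5p had 0. Reads that match several loci may have been left uncounted, a hypothesis on the counting, and no biological explanation was tested. miR-92a-3p (1516 counts) and miR-19b-3p (112 counts) are exceptions.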
